A study of Macaca mulatta with 60 samples.

How the data were processed

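Gene expression was measured in 60 whole blood samples of 8 female rhesus macaques, 1 Affymetrix rhesus array per sample. Per the labels' protocols, blood was drawn into RNA-preserving tubes, total RNA was amplified through a pair of labelling cycles with biotin, with globin blockers added, and the labelled RNA was hybridized in 4 batches. The authors' deposited values are on a log2 scale, 1 value for each of 52865 probe sets per array. Partek is named in the submitters' processing notes. The background correction, normalization and summary method behind the deposited log2 values, and the version of Partek, are not given in the sources used here, and the log2 scale itself rests on the range of the values (2.93 to 15.4) and their spread. Each array's mean lay between 6.38 and 6.40, its median between 5.83 and 6.08 and its SD between 1.73 and 2.01. The mean correlation of an array with the others was between 0.955 and 0.983. Depth has no meaning for these arrays.

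Samples were grouped by the study day and the arm in their labels, which gave 11 groups. The array labels give a drawing date for each sample, and for 4 arrays that date lay more than 5 days from the labelled study day (the array of RZl5 labelled day 31 and the arrays of RWf7 labelled days 171, 182 and 189). As a study day, the date of the RZl5 array was day 217, and those of the RWf7 arrays were days 182, −176 and 213. By date, the RWf7 array labelled day 171 would follow the antibody of day 177, and that labelled day 182 would precede infection. All 4 arrays stayed in the groups their labels give, and were left out or regrouped by date as alternatives. The hybridization batches each hold 1 animal of each arm, so batch is contained in the animal term. The chamber batch was the same for all arrays of an animal except in RLi6, whose arrays labelled days 63 and 70 went through another chamber batch than its other 4 arrays, and leaving out RLi6 covers this. All value columns of the table were used.

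Probe sets were named through the platform annotation supplied with the data. A single gene symbol was listed for 24969 probe sets, several for 361 and none for 27535. Of the probe sets with 1 symbol, 24629 were matched by gene ID to the current gene table, which changed 0 symbols. Probe sets with several symbols or none entered no test of genes. For each of 14132 genes the probe set with the highest mean over all arrays was kept, and genes whose mean lay under the 25th percentile of all probe sets (5.01 log2) were left out, which left 12410 genes tested. For CD8A and CD8B the other probe set was also read.

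The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes). A single fit held all 60 arrays with a mean for each arm and time point and the animal as a fixed block (residual df 38, prior df 4.33). Contrasts over both arms average the arms. A fold change is therefore a difference of fitted means, and standard errors come from the spread that all groups share. Adjusted p values are Benjamini-Hochberg values over the 12410 genes of a comparison, with a threshold of 0.05. All limma tests were two-sided. There were 15 comparisons: days 10, 14, 31, 171 and later chronic infection against the uninfected sample, the changes after the early and the late antibody, the changes over the week after each, the drugs without antibody, the net changes over both steps, and differences between the arms. Changes of single values per animal were tested with exact two-sided sign-flip permutation tests, which with 4 animals cannot go below p = 0.125.

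The arrays of 1 animal form pairs by the labels' animal names. After removal of group means, arrays of the same animal correlated with a mean r of 0.4 over 202 pairs of arrays (0.157 to 0.562 per animal), and arrays of other animals of the same arm with −0.132 over 608 pairs.

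A set of 23 gene lists (504 genes, of which 353 were found and 340 tested) was written from textbook knowledge: CD8 coreceptor, cytotoxic lymphocyte, NK cell, pan T cell, CD4 and naive T cell, B cell, plasma cell, monocyte, mature neutrophil, granule and immature neutrophil, erythroid, platelet, interferon-stimulated, interferon-gamma and guanylate-binding, proliferation, inflammatory cytokine and NF-kappa-B, T cell inhibitory and regulatory, common gamma chain cytokine, MHC class II and antigen presentation, complement and macrophage activation, restriction factor, ribosomal protein, and handling and immediate early genes. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated from the data. Adjusted p values of camera are over all 330 list tests. Members were also counted after adjustment over the list alone. The CD8 coreceptor list was read gene by gene. Lists share some members and are not independent. CD8A and CD8B, the targets of the antibody, are also in the cytotoxic lymphocyte list. SIGLEC1, BST2, SERPING1, CD244 and CD160 are each in several lists.

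For each comparison the genes named are CD8A and CD8B, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with the same sign in every animal (for a difference of changes, in the group means), and up to 4 members of each list with the largest change. A gene named in one comparison may be given in the others. This rule, the lists, the groups, the tests and a first set of alternatives were fixed before the data were examined.

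That first set held fits without the animal block, with the animal as a random block, with only the arrays compared, with no filter, with a filter at the median of all probe sets (5.92 log2), with all probe sets in place of 1 per gene, with quantile normalization on top of the deposited values, with each array centred on its median, with trend and robust options of eBayes, with array weights, with the discordantly dated arrays left out or regrouped, with each animal left out in turn, and with other references for the difference at day 70. Added after the data were seen were fits without a pair of arrays of RPp6 or of RZl5, with the SD of each array or the mean of the erythroid list as a covariate, and with the uninfected sample as the reference for the early depletion and for the difference between depletions.

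The fit was tested for 3 of the 15 comparisons on simulated data with 50 genes changed at each of 4 sizes, among 12410 genes. In the simulated day 10 comparison 84% of genes changed by 0.5 log2 were called, 98% of those changed by 1, 100% at 2 and 100% at 3, and 0.0819% of unchanged genes. In the simulated late depletion the shares were 42%, 94%, 100% and 100%, and 0.0983% of unchanged genes. For the simulated difference between depletions they were 34%, 82%, 98% and 100%, and 0.0573% of unchanged genes. These shares hold for the simulated data, and its match to the real arrays was not tested. Tables, correlations and permutation tests used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.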

Results

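Blood of 8 female rhesus macaques infected with SIVmac239, a cloned simian immunodeficiency virus, was profiled on 60 whole-genome expression arrays. The animals were sampled before infection (uninfected, 8 arrays), at day 10 of infection (8 arrays, drawn on day 9 by their labels), at day 14 (7 arrays, none of RLi6) and at day 31 (8 arrays). In arm A (RLi6, RPp6, RRf6 and RZl5) the CD8-binding antibody OKT8F, which depletes CD8+ lymphocytes from blood, was given at day 58, and the reverse transcriptase inhibitors tenofovir and emtricitabine (ART) started at day 63. Arm A was sampled at days 63 and 70 (4 arrays each). Arm B (RSq8, RUe7, RWf7 and XHB) had a sham injection at day 58 and the same drugs from day 63, with arrays at day 70 (4 arrays). Arm B then received the antibody at day 177 and the drugs from day 182, with arrays at days 171, 182 and 189 (4 each). Chronic infection after day 180 was sampled in 5 animals, 2 of arm A and 3 of arm B. The number of arrays limits the precision of every value. Values are log2 changes with the standard error (SE) of the limma fit or, for the mean of a gene list, the SD over animals. The day 31 arrays had the narrowest spread of values within an array (SD 1.85 ± 0.06 over 8 arrays, against 1.92 ± 0.02 in the 8 uninfected arrays). Testing all probe sets in place of 1 per gene raised the counts of most comparisons by over 1.5 times, as did array weights, whose estimation did not converge, and these counts stand with the other processing alternatives. Of 330 list tests, 132 passed the threshold with the preset correlation (76 higher, 56 lower) and 0 with an estimated correlation, where the smallest adjusted p was 0.157 and 34 tests had an unadjusted p under 0.05.

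The targets of the antibody were read first. CD8A and CD8B encode the chains of the CD8 coreceptor. After the late antibody, CD8A fell by 1.81 ± 0.32 between days 171 and 182, and CD8B fell by 1.32 ± 0.31 (limma adjusted p = 0.003 and 0.029), and both were lower in 4 of 4 animals. A further CD8A probe set changed by −1.56 and a further CD8B probe set by −0.72, each in 4 of 4 animals. After the early antibody, between day 31 and the arrays labelled day 63, CD8A differed by −0.48 ± 0.32 and CD8B by −0.53 ± 0.31 (limma adjusted p = 0.21 and 0.153), neither past the threshold. CD8A was lower in 3 of 4 animals and CD8B in 4 of 4 (exact sign-flip permutation p = 0.25 and 0.13, where 0.13 is the smallest that 4 animals allow). The further probe sets changed by −0.42 (CD8A) and −0.23 (CD8B), each lower in 3 of 4 animals. The array of RZl5 labelled day 63 had a CD8A level of 11.9, against 10.2 to 10.4 in the other arm A animals and 11.73 in RZl5 at day 31, and so the target goes against its label. This array is called the array labelled day 63 throughout, and each direction drawn from arm A at days 63 and 70 includes it unless stated. Across infection, CD8B fell at day 10 by 0.60 ± 0.22 (limma adjusted p = 0.0323, lower in 6 of 8 animals). At day 14 CD8A and CD8B rose by 0.65 ± 0.24 and 0.77 ± 0.23 (adjusted p = 0.0393 and 0.0116 in limma, in 7 and 6 of 7 animals). These calls were lost without the animal block (adjusted p = 0.165, 0.126 and 0.126 in limma). That at day 10 was also lost without any one of RLi6, RRf6, RSq8, RUe7, RZl5 or XHB (limma adjusted p = 0.0795, 0.0514, 0.142, 0.06, 0.0595 and 0.0882) and after quantile normalization (adjusted p = 0.0599). At day 14 that of CD8A was lost without RRf6, RUe7, RWf7 or RZl5 (limma adjusted p = 0.11, 0.0664, 0.224 and 0.102) and after quantile normalization (adjusted p = 0.0683), that of CD8B without RRf6, RWf7 or RZl5 (adjusted p = 0.0529, 0.0907 and 0.054), and both with the erythroid mean as a covariate (adjusted p = 0.35 and 0.285). Neither passed at day 31, at day 171 or in chronic infection. CD8A at day 10 gained a call without RPp6 (−0.58, limma adjusted p = 0.0385). The call of CD8B after the late antibody was lost without RSq8, RUe7, RWf7 or XHB (limma adjusted p = 0.226, 0.0706, 0.104 and 0.285), without the animal block (adjusted p = 0.365) and without the discordantly dated arrays (adjusted p = 0.122). That of CD8A was lost without RSq8 (adjusted p = 0.063) or XHB (adjusted p = 0.101) and with arrays regrouped by drawing date (−1.43, adjusted p = 0.603).

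**Figure D1:**
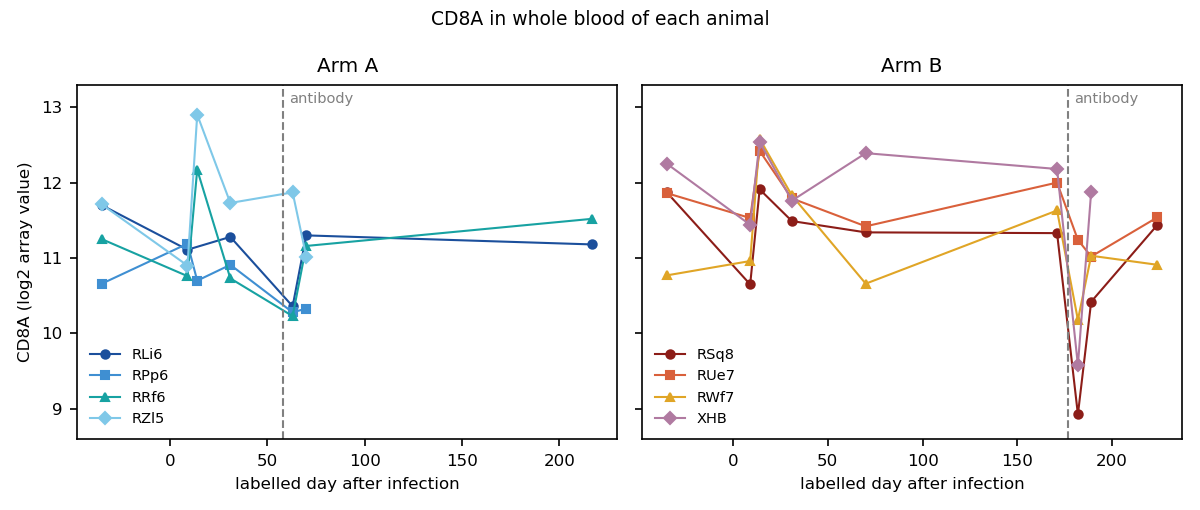
CD8A level (log2) in each animal against the labelled day of infection, with a panel for each arm and a dashed line at the day of the antibody. In arm B all 4 animals were lower at day 182 than at day 171, and in arm A the array of RZl5 labelled day 63 (11.9) stands above those of the other 3 animals (10.2 to 10.4).

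Day 10 against the uninfected sample addressed the first response of blood to the virus. Antiviral genes induced by type I interferon had the largest rises. ISG15, a ubiquitin-like antiviral protein, rose by 4.98 ± 0.54, IFI27 by 4.77 ± 0.44 and CMPK2 by 4.00 ± 0.53. Each rose in 8 of 8 animals (limma adjusted p = 2.91e-09, 1.24e-10 and 2.27e-07). Host factors that block retroviruses rose too, among them MX2 (2.68 ± 0.30), the virion tether BST2 (1.60 ± 0.22), the capsid-binding TRIM5 (1.29 ± 0.20) and the cytidine deaminase APOBEC3H (0.99 ± 0.14). B cell genes and CD14, the lipopolysaccharide coreceptor of monocytes, fell. In all, 3972 of 12410 genes passed limma's threshold (1664 higher, 2308 lower), 200 of them by at least 2-fold, of which 159 were higher.

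Of 39 interferon-stimulated genes 36 rose and 3 fell at day 10 (36 and 3 adjusted over the list alone), and their mean was 2.11 ± 0.51 higher (SD, n = 8). Camera gave adjusted p = 3.05e-33, and adjusted p = 0.201 with an estimated correlation. All 7 restriction factors rose (7 adjusted over the list alone, mean 1.20 ± 0.22, camera adjusted p = 5.1e-07; adjusted p = 0.157 with an estimated correlation). Of 17 interferon-gamma and guanylate-binding genes 13 rose (13 adjusted over the list alone), with the chemokine CXCL10 at 2.81 ± 0.30 and GBP1 at 2.16 ± 0.28, and the list mean was 0.88 ± 0.30 higher. This list passed camera (adjusted p = 9.2e-09) and had adjusted p = 0.358 with an estimated correlation. Among 11 complement and macrophage activation genes 8 rose (8 adjusted over the list alone), including SIGLEC1, a sialic acid receptor of activated macrophages (2.67 ± 0.27), and C1QA (1.18 ± 0.20). This list passed camera (adjusted p = 3.36e-05) and had adjusted p = 0.201 with an estimated correlation. Inflammatory cytokine and NF-kappa-B genes rose in 6 of 16 and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0131, and adjusted p = 0.485 with an estimated correlation), led by IL1RN, the interleukin-1 receptor antagonist (3.15 ± 0.30), and TNFAIP6 (2.66 ± 0.36). Handling and immediate early genes, which also respond to the time blood stands after drawing, rose in 3 of 13 (3 adjusted over the list alone; camera adjusted p = 0.0368, and adjusted p = 0.668 with an estimated correlation), with ATF3 at 2.21 ± 0.21.

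Genes of particular blood cells moved at day 10 as well. Of 12 B cell genes 7 fell (8 adjusted over the list alone), including MAMU-DOB (−1.02 ± 0.15) and the B cell transcription factor EBF1 (−0.87 ± 0.21), and the mean was −0.49 ± 0.19 in 8 animals. In the camera test the list had adjusted p = 0.00259, and adjusted p = 0.598 with an estimated correlation. Platelet genes rose in 11 of 15 and fell in 1 (11 and 1 adjusted over the list alone), among them TREML1 (1.04 ± 0.22) and the chemokine PPBP (0.75 ± 0.19). In the camera test the list had adjusted p = 7.99e-05, and adjusted p = 0.485 with an estimated correlation. Ribosomal protein genes fell in 16 of 24 (18 adjusted over the list alone), such as RPL10A (−0.79 ± 0.18) and RPL8 (−0.73 ± 0.14). As a list they passed camera (adjusted p = 5e-07) and had adjusted p = 0.479 with an estimated correlation. Monocyte genes moved both ways, 5 up and 3 down of 15 (5 and 3 adjusted over the list alone; camera adjusted p = 0.397), CD14 by −1.41 ± 0.25 and FCN1 by 1.25 ± 0.24, while 5 of 18 cytotoxic lymphocyte genes fell (5 adjusted over the list alone; camera adjusted p = 0.169). Without RSq8 the count of genes was 2024. Between its arrays labelled days 10 and 14 RPp6 changed opposite to the other animals, and without these arrays 5732 genes passed.

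At day 14 the question was how the acute response developed near the peak of infection. Cell division genes led: TYMS, which makes thymidylate for DNA synthesis, rose by 2.90 ± 0.25, the mitotic cyclin CCNB2 by 2.47 ± 0.22 and MKI67 by 1.92 ± 0.21 (limma adjusted p = 3.53e-11, 1.11e-10 and 3.54e-09), each in 7 of 7 animals. Genes of killer lymphocytes rose with them, including the proteases GZMB (1.52 ± 0.28) and GZMH (1.26 ± 0.34), the pore-forming GNLY (1.23 ± 0.33) and the inhibitory receptor LAG3 (1.60 ± 0.19). Red cell genes were lower, with KLF1, the master regulator of erythroid genes, at −2.59 ± 0.45 and EPB42 at −2.36 ± 0.44. The test called 2901 genes (2086 higher, 815 lower), of which 287 changed at least 2-fold.

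Among the 26 proliferation genes 24 rose at day 14 (24 adjusted over the list alone), and the mean was 1.35 ± 0.56 higher (SD, n = 7). As a list they passed camera (adjusted p = 6.7e-32) and had adjusted p = 0.157 with an estimated correlation. Cytotoxic lymphocyte genes rose in 12 of 18 (13 adjusted over the list alone, mean 0.68 ± 0.49), with camera adjusted p = 0.000118 and adjusted p = 0.616 with an estimated correlation, and 1 of 13 NK cell genes rose. Interferon-stimulated genes rose in 28 of 39 (29 adjusted over the list alone), with a mean of 1.10 ± 0.90, positive in 5 of 7 animals. The camera test gave adjusted p = 4.34e-11, and adjusted p = 0.485 with an estimated correlation. B cell genes fell in 10 of 12 (11 adjusted over the list alone), with FCRL1 at −1.31 ± 0.23 and MS4A1, which encodes CD20, at −0.997 ± 0.22. Camera gave adjusted p = 6.5e-07, and adjusted p = 0.463 with an estimated correlation. Plasma cell genes rose in 5 of 10 (6 adjusted over the list alone), including JCHAIN, the joining chain of secreted antibodies (1.07 ± 0.26), and TNFRSF17 (0.92 ± 0.25). The camera test gave adjusted p = 0.00505, and adjusted p = 0.529 with an estimated correlation. Of 13 MHC class II and antigen presentation genes 6 fell (6 adjusted over the list alone), among them CD74 (−0.77 ± 0.20), MAMU-DQA1 (−0.74 ± 0.18) and CD1C (−1.03 ± 0.19). Camera gave adjusted p = 0.000263, and adjusted p = 0.463 with an estimated correlation. T cell inhibitory and regulatory genes rose in 4 of 15 and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.265).

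Erythroid genes fell in 10 of 15 at day 14 (11 adjusted over the list alone), and the mean was −0.98 ± 0.99, negative in 6 of 7 animals. This list passed camera (adjusted p = 4.03e-06) and had adjusted p = 0.485 with an estimated correlation. Platelet genes rose in 10 of 15 (11 adjusted over the list alone), with GP1BA at 0.81 ± 0.14. In the camera test the list had adjusted p = 4.75e-05, and adjusted p = 0.485 with an estimated correlation. Monocyte genes rose in 7 of 15 and fell in 1 (9 and 1 adjusted over the list alone), and mature neutrophil genes rose in 5 of 13 (5 adjusted over the list alone), with camera adjusted p = 0.0101 and 0.0368, and adjusted p = 0.668 with an estimated correlation for both. The calgranulin S100A9 rose by 1.41 ± 0.27 and the haemoglobin scavenger HP by 2.31 ± 0.41. The count of genes was 1831 without RWf7, 1881 without the animal block and 1864 with the erythroid mean of each array as a covariate. It was 4108 without the doubted arrays of RPp6.

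Day 31 asked what remained of the acute response before any treatment. Interferon genes stayed high, with IFI27 at 4.48 ± 0.44 and ISG15 at 2.87 ± 0.54 above the uninfected sample (limma adjusted p = 9.37e-09 and 0.000167, 8 of 8 animals). Genes of antibody-secreting cells were up, JCHAIN by 1.64 ± 0.25 and TNFRSF17 by 1.49 ± 0.24, and so were genes of young red cells, the fetal globin HBG2 by 2.49 ± 0.48 and the hormone ERFE by 1.98 ± 0.60. Lower were the T cell genes for the transcription factor TCF7 (−1.05 ± 0.19), CD40LG (−0.87 ± 0.15), the lymph node homing receptor CCR7 (−0.79 ± 0.17) and CD4 (−0.44 ± 0.12). The fit called 5288 genes (2649 higher, 2639 lower), but only 90 of them changed at least 2-fold.

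Of the interferon-stimulated genes 26 of 39 rose and 4 fell at day 31 (29 and 4 adjusted over the list alone), with a mean of 1.02 ± 0.65 in 8 animals. As a list they passed camera (adjusted p = 2.66e-07) and had adjusted p = 0.598 with an estimated correlation. Proliferation genes rose in 21 of 26 (23 adjusted over the list alone), including TYMS (1.68 ± 0.24) and MCM10 (1.17 ± 0.17). This list passed camera (adjusted p = 1.66e-12) and had adjusted p = 0.463 with an estimated correlation. Plasma cell genes rose in 6 of 10 (7 adjusted over the list alone; camera adjusted p = 0.00184, and adjusted p = 0.485 with an estimated correlation). Erythroid genes rose in 7 of 15 and fell in 1 (9 and 1 adjusted over the list alone), and the mean was 0.70 ± 0.40 higher, in 8 of 8 animals. The camera test gave adjusted p = 0.0106, and adjusted p = 0.701 with an estimated correlation. Ribosomal protein genes fell in 13 of 24 (13 adjusted over the list alone), RPL32 by −0.50 ± 0.10. In the camera test the list had adjusted p = 0.002, and adjusted p = 0.668 with an estimated correlation. The T cell lists did not pass as lists: 4 of 8 CD4 and naive T cell genes fell (4 adjusted over the list alone, camera adjusted p = 0.0836), as did 6 of 12 pan T cell genes while 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.144), with CD5 at −0.74 ± 0.14. Common gamma chain cytokine genes fell in 5 of 12 and rose in 2 (6 and 3 adjusted over the list alone, camera adjusted p = 0.429). The inflammatory genes IL1B and SOD2 fell by 0.81 ± 0.18 and 0.72 ± 0.19. Without XHB 3269 genes passed, with the SD of each array as a covariate 1704, and with its erythroid mean as a covariate 1757. Quantile normalization gave 2997 higher and 1932 lower genes (60.8% higher, against 50.1% as deposited), and centring 1657 and 3054 (35.2% higher).

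**Figure D2:**
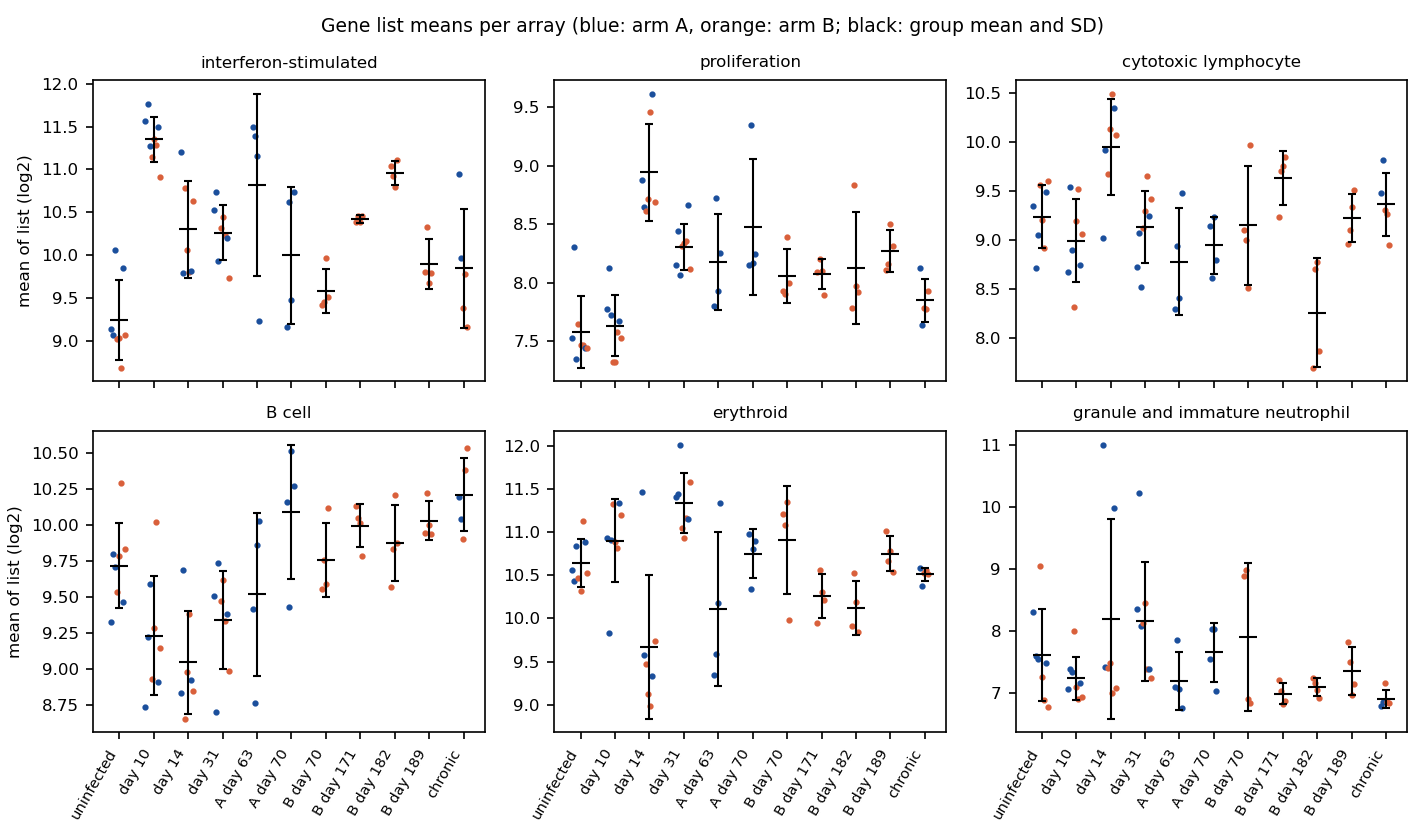
Mean log2 level of 6 gene lists in each array by group, with arm A in blue, arm B in orange, and the group mean and SD in black. The erythroid mean is 0.70 higher at day 31 than in the uninfected sample and the interferon-stimulated mean 2.11 higher at day 10.

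Chronic infection after day 180 was compared with the uninfected sample in 5 animals, all given the antibody and drugs before. IFI27 remained raised by 2.54 ± 0.52 (adjusted p = 0.00656 in limma, 5 of 5 animals) and IFI44 by 2.02 ± 0.46 (adjusted p = 0.0198, 4 of 5). The transcriptional repressor ZBTB32 was higher by 1.47 ± 0.29, TNFRSF13B, a receptor for B cell survival factors, by 1.03 ± 0.17 and the B cell surface protein CD22 by 0.81 ± 0.20. Among the genes that fell were WIF1 (−1.11 ± 0.27) and SFRP5 (−0.93 ± 0.20), secreted inhibitors of Wnt signalling, and AXIN2 (−0.82 ± 0.19). Only 86 genes passed (43 higher, 43 lower).

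In chronic infection 2 of 39 interferon-stimulated genes rose (7 adjusted over the list alone), mean 0.69 ± 0.72. Camera gave adjusted p = 3.94e-15, and adjusted p = 0.463 with an estimated correlation. Of 12 B cell genes 1 rose (8 up and 1 down adjusted over the list alone), mean 0.39 ± 0.25, higher in 5 of 5 animals. This list passed camera (adjusted p = 1.52e-05) and had adjusted p = 0.477 with an estimated correlation. No proliferation gene passed over all genes (limma; 4 adjusted over the list alone), though the list mean of 0.36 ± 0.18 gave camera adjusted p = 6.13e-11 and adjusted p = 0.479 with an estimated correlation. Platelet and granule genes had means of −0.29 ± 0.42 and −0.69 ± 0.76 with 0 members past limma's threshold (camera adjusted p = 2.27e-05 and 0.000409, and adjusted p = 0.479 and 0.509 with an estimated correlation). The count of 86 was 0 in a fit of only the arrays compared (1916 genes at unadjusted p under 0.05), 21 without the animal block, 51 with a random block, 132 after quantile normalization, 57 after centring, 234 with the array SD and 169 with the erythroid mean as a covariate. It was 0 without RLi6 (520 at unadjusted p under 0.05), 18 without RUe7, 34 without RSq8, 43 without XHB and 190 without RPp6.

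Arm B was compared with its uninfected sample at day 171, before the late antibody. IFI27 was 4.74 ± 0.63 above the uninfected level, IFI44 3.77 ± 0.56, ISG15 3.53 ± 0.77 and the antiviral GTPase MX1 3.23 ± 0.56, each in 4 of 4 animals (limma adjusted p = 2.79e-05, 0.000183, 0.0267 and 0.00392). TYMS (1.41 ± 0.33) and the lymphocyte growth factor IL15 (1.06 ± 0.25) rose as well, and IL11RA (−0.70 ± 0.15) and IGF1R (−0.65 ± 0.15) fell. Of 39 interferon-stimulated genes 11 rose (29 adjusted over the list alone), mean 1.47 ± 0.15. In the camera test the list had adjusted p = 9.47e-37, and adjusted p = 0.179 with an estimated correlation. Proliferation genes rose in 1 of 26 (20 adjusted over the list alone; camera adjusted p = 6.48e-16, and adjusted p = 0.463 with an estimated correlation). The monocyte list, with 0 of 15 members past limma's threshold (1 adjusted over the list alone), had a mean of 0.43 ± 0.33. As a list they passed camera (adjusted p = 0.000193) and had adjusted p = 0.501 with an estimated correlation. In all 32 genes passed (18 higher, 14 lower). The count was 9 without the animal block, 21 with a random block, 467 with only the arrays compared, 64 after quantile normalization, 14 after centring (11 higher, 3 lower), 69 and 56 with the array SD and the erythroid mean as covariates, 7 without the discordantly dated arrays and 5 with them regrouped. Without RSq8, RUe7, XHB or RWf7 it was 2, 3, 7 or 9.

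The early antibody was read between day 31 and the arrays of arm A labelled day 63, 5 days after the injection and 32 days after the reference. Genes of neutrophil granules and their precursors fell: CRISP3 by 3.87 ± 1.10, the iron-binding LCN2 by 2.67 ± 0.68, the collagenase MMP8 by 2.58 ± 0.80 and the defensin DEFA1 by 2.65 ± 0.80, in 4 of 4 animals (limma adjusted p = 0.0109, 0.00719, 0.0155 and 0.0138). Red cell genes fell, HBG2 by 3.02 ± 0.67 and AHSP by 1.91 ± 0.54, in 3 of 4 animals each. RZl5, whose reference is discordantly dated, showed no fall. Of interferon-induced genes, BST2 rose by 1.11 ± 0.31, GBP2 by 1.43 ± 0.41 and TAP1 by 0.92 ± 0.24. CD274 (PD-L1) rose by 1.14 ± 0.32, and all rose in the 3 animals other than RZl5. IL15 and its receptor IL15RA rose by 0.70 ± 0.25 and 0.58 ± 0.16, the latter in 4 of 4 animals. The test called 4644 genes (2328 higher, 2316 lower), 234 of them by at least 2-fold, of which 192 were lower.

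Erythroid genes fell in 14 of 15 and rose in 1 after the early antibody (14 and 1 adjusted over the list alone), mean −1.39 ± 1.06 (SD, n = 4). The camera test gave adjusted p = 7.85e-06, and 0.485 with an estimated correlation. Of 14 granule and immature neutrophil genes 7 fell (9 adjusted over the list alone), mean −1.32 ± 0.75. Camera gave adjusted p = 0.00117, and 0.544 with an estimated correlation. Interferon-stimulated genes rose in 9 of 39 (8 adjusted over the list alone), mean 0.47 ± 0.98. This list passed camera (adjusted p = 0.00299), with 0.777 for an estimated correlation. Interferon-gamma and guanylate-binding genes rose in 7 of 17 and fell in 1 (7 and 2 adjusted over the list alone), and handling genes rose in 4 of 13 (3 adjusted over the list alone), ATF3 by 0.99 ± 0.29 and IER2 by 0.98 ± 0.18. In camera these lists had adjusted p = 0.0403 and 0.0308, and 0.701 and 0.659 with an estimated correlation. The lists of killer cells did not pass: 1 of 18 cytotoxic and 2 of 13 NK cell genes rose (1 and 1 adjusted over the list alone), with means of −0.11 ± 0.27 and 0.04 ± 0.24 (camera adjusted p = 0.761 and 0.983). The cytotoxic mean includes CD8A (−0.48) and CD8B (−0.53). Of 12 pan T cell genes 4 fell, and the T cell genes CD28 and CD96 fell by 0.53 ± 0.13 and 0.52 ± 0.13. The erythroid mean and the array spread both differed between day 31 and the arrays labelled day 63. The array SD was 1.85 ± 0.06 in 8 and 1.96 ± 0.05 in 4 arrays.

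Measured from the uninfected sample in place of day 31, the arrays labelled day 63 differed in 550 genes (401 higher, 149 lower). Again past the threshold were GBP2 (1.78, limma adjusted p = 0.00971), TAP1 (0.87, 0.0262), ATF3 (1.21, 0.0124) and BST2 (1.37, 0.00942). So were CD274 (1.14, 0.0329), IL15 (1.01, 0.0142) and IL15RA (1.04, 0.000288). Not past it were HBG2 (−0.37, adjusted p = 0.782), LCN2 (−1.51, 0.213), CRISP3 (−2.31, 0.243), MMP8 (−1.26, 0.395) and DEFA1 (−1.37, 0.356). Nor were AHSP (−0.91, 0.364), CD28 (−0.31, 0.186), CD96 (−0.23, 0.337) and IER2 (0.46, 0.143). The 4644 genes called against day 31 became 6003 without the arrays of RZl5 labelled days 63 and 70, 1556 without RPp6, 2 without RRf6 and 0 without RLi6 (3679 at unadjusted p under 0.05), and 0 in a limma fit of only the arrays compared (3508 at unadjusted p under 0.05) or with the array SD (1251) or the erythroid mean (719) as a covariate. Quantile normalization gave 1194 higher and 1819 lower genes (39.6% higher, against 50.1%), and centring, which moved the median change of all genes from 0.0387 to 0.154, 3279 and 1282 (71.9% higher).

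Between the arrays labelled days 63 and 70 of arm A, the first 7 days of drugs, no gene passed the threshold in limma (1501 at unadjusted p under 0.05, smallest adjusted p = 0.0611). CD8A differed by 0.26 ± 0.32 and CD8B by 0.22 ± 0.31, each higher in 3 of 4 animals. The interferon-stimulated mean was −0.82 ± 1.68 (0 of 39 past the threshold, 8 down adjusted over the list alone), negative in 3 of 4 animals and positive in RZl5, whose list mean rose from 9.23 on the array labelled day 63 to 10.74 on that labelled day 70. The B cell mean was 0.57 ± 0.23 higher in 4 of 4 animals (6 of 12 genes up adjusted over the list alone). For these lists camera gave adjusted p = 8.39e-17 and 1.42e-06, and adjusted p = 0.463 with an estimated correlation for each. Platelet and erythroid genes had means of −0.45 ± 0.43 and 0.64 ± 0.86 (3 down and 0 adjusted over the list alone). The monocyte mean was −0.47 ± 0.76, lower in the same 3 animals as the interferon-stimulated mean. Of its 15 members 0 passed limma's threshold (1 down adjusted over the list alone). These lists had camera adjusted p = 8.93e-07, 0.000533 and 4.67e-06, and 0.463, 0.609 and 0.463 with an estimated correlation. In all 12 of 22 lists passed camera, 5 higher and 7 lower. Without RZl5 1493 genes passed, without only its arrays labelled days 63 and 70 1434, after quantile normalization 2, and with the array SD or the erythroid mean as a covariate 68 or 118. A further CD8A probe set gave −0.0037.

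Arm B between days 31 and 70, without the antibody, spans 32 days of untreated infection and 7 days of drugs, which no test separates. IFI27 fell by 2.61 ± 0.63 and SIGLEC1 by 1.54 ± 0.39, in 4 of 4 animals (limma adjusted p = 0.0278 and 0.0412). Genes that rose included PADI4 (1.41 ± 0.30), HAL (0.95 ± 0.22) and CLEC4E (1.56 ± 0.36). SERPINE2 and BDKRB2 rose by 2.01 ± 0.36 and 1.48 ± 0.25, and both had fallen at day 10. Of 39 interferon-stimulated genes 2 fell (2 adjusted over the list alone), mean −0.59 ± 0.41. Camera gave adjusted p = 9.09e-05, and 0.701 with an estimated correlation. Mature neutrophil genes rose in 2 of 13 (5 adjusted over the list alone), mean 0.56 ± 0.41 (camera adjusted p = 0.000133; adjusted p = 0.463 with an estimated correlation), and the B cell mean was 0.40 ± 0.49 (1.13 in XHB, 0.0782 to 0.256 in the other 3 animals) with 0 of 12 members past limma's threshold (0 adjusted over the list alone; camera adjusted p = 0.000263, and adjusted p = 0.509 with an estimated correlation). The fit called 95 genes (89 higher, 6 lower), 6 without the animal block, 42 with a random block and 3 with only the arrays compared, and after quantile normalization 84 higher and 27 lower (75.7% higher, against 93.7%). Without RSq8 the count was 0 (limma; 1126 at unadjusted p under 0.05) and without XHB 17.

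The late antibody, read in arm B between days 171 and 182 (5 days after the injection), was followed by lower levels of killer lymphocyte genes. GZMH fell by 2.81 ± 0.46, the NK cell receptor KLRF1 by 2.58 ± 0.46, GNLY by 2.18 ± 0.44, FGFBP2 by 2.13 ± 0.37, NKG7 by 2.01 ± 0.36 and GZMB by 2.00 ± 0.38, each in 4 of 4 animals (limma adjusted p = 0.00302, 0.00302, 0.0067, 0.00302, 0.00305 and 0.00426). S1PR5 (−1.91 ± 0.37), CTSW (−1.74 ± 0.35), KLRK1 (−1.26 ± 0.26) and CD244 (−0.96 ± 0.21) fell too. The few genes that rose included NEURL3 (0.89 ± 0.17), GFPT2 (0.75 ± 0.16) and TICAM1 (0.57 ± 0.14). The test called 67 genes (10 higher, 57 lower), all 67 with the same sign in 4 of 4 animals, 29 of them at least 2-fold lower. These 4 animals include RWf7, whose arrays labelled days 171 and 182 are discordantly dated. As labelled, its change over genes had r = 0.672 with the others' mean (0.326 to 0.537 for them). Whether dates or labels are wrong stays open.

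Of 18 cytotoxic lymphocyte genes, CD8A and CD8B among them, 11 fell after the late antibody (15 adjusted over the list alone), mean −1.37 ± 0.48 (SD, n = 4; camera adjusted p = 2.63e-28). Of 13 NK cell genes 3 fell (6 adjusted over the list alone), mean −0.85 ± 0.15 (camera adjusted p = 5.23e-11), and for both lists adjusted p = 0.157 with an estimated correlation. Pan T cell genes had a mean of −0.22 ± 0.05, lower in 4 of 4 animals. Of 12 members 0 passed limma's threshold (3 down adjusted over the list alone). The interferon-stimulated mean was 0.54 ± 0.12 higher in 4 of 4 animals, with 0 of 39 members past it (0 adjusted over the list alone). These lists had camera adjusted p = 0.0113 and 2.67e-05, and 0.501 and 0.694 with an estimated correlation. The erythroid mean differed by −0.14 ± 0.15 (camera adjusted p = 0.289). The count was 25 without the animal block, 31 without the discordantly dated arrays, 0 with them regrouped by date (limma; 660 at unadjusted p under 0.05), 291 with only the arrays compared, 232 and 345 with the array SD and the erythroid mean as covariates, and after quantile normalization 32 higher and 62 lower (34% higher, against 14.9%). Without XHB it was 0 (limma; 1366 at unadjusted p under 0.05), without RSq8 or RUe7 13, and without RWf7 43.

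**Figure D3:**
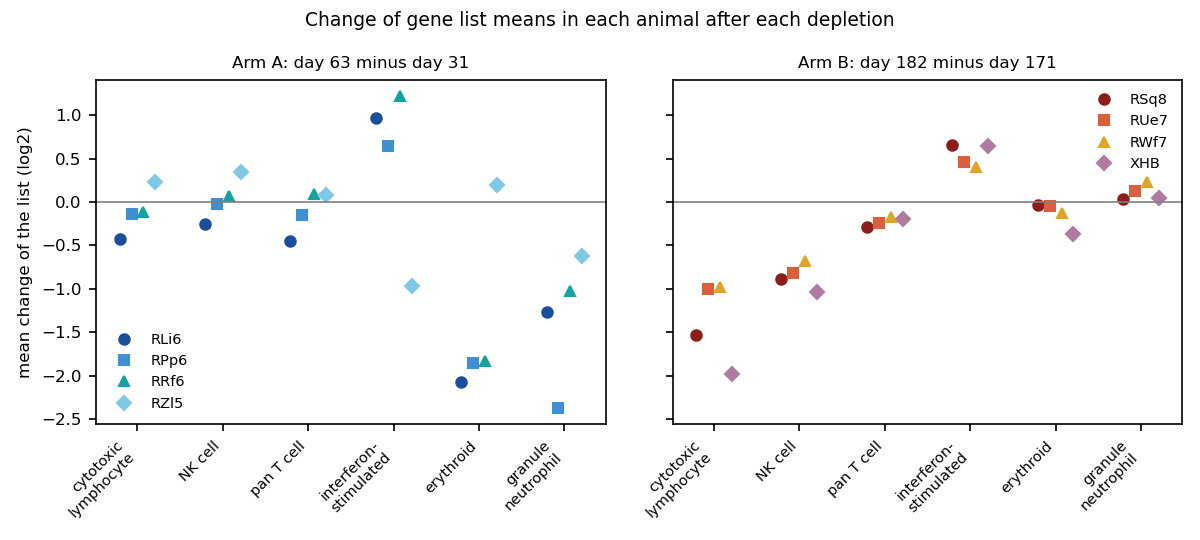
Change of the mean log2 level of 6 gene lists in each animal after the early antibody (arm A, arrays labelled day 63 minus day 31) and the late antibody (arm B, day 182 minus day 171). The cytotoxic mean changed by −1.37 after the late antibody and −0.11 after the early one, and the erythroid mean by −0.14 and −1.39.

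From day 182 to day 189, the first week of the second course of drugs, several killer lymphocyte genes returned. KLRF1 rose by 2.18 ± 0.46, GZMH by 2.14 ± 0.46, GNLY by 2.00 ± 0.44, NKG7 by 1.56 ± 0.36 and GZMB by 1.54 ± 0.38, each in 4 of 4 animals (limma adjusted p = 0.0234, 0.0235, 0.0235, 0.0343 and 0.0448). SIGLEC1 fell by 2.23 ± 0.39 and SPATS2L by 1.79 ± 0.44. CD8A differed by 1.11 ± 0.32 (adjusted p = 0.079 in limma), higher in 3 of 4 animals, and passed without RUe7 (adjusted p = 0.0451), after quantile normalization (0.039) and with the array SD (0.0271) or the erythroid mean (0.0188) as a covariate. In all 73 genes passed (32 higher, 41 lower). The arrays of RWf7 labelled days 182 and 189 are discordantly dated. As labelled, its r with the others' mean change was 0.65 (0.162 to 0.679 for them).

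Cytotoxic lymphocyte genes rose in 6 of 18 over that week (14 adjusted over the list alone), mean 0.96 ± 0.58. NK cell genes rose in 2 of 13 (6 adjusted over the list alone), mean 0.72 ± 0.24. These lists had camera adjusted p = 4.15e-15 and 1.26e-07, and 0.361 and 0.294 with an estimated correlation. Interferon-stimulated genes fell in 2 of 39 (30 adjusted over the list alone), mean −1.07 ± 0.33 in 4 of 4 animals. The camera test gave adjusted p = 8.76e-20, and adjusted p = 0.463 with an estimated correlation. The erythroid mean was 0.63 ± 0.39 higher and the platelet mean −0.36 ± 0.24, lower in 4 of 4 animals. Both had 0 of 15 members past limma's threshold and 0 adjusted over the list alone. Camera gave them adjusted p = 0.000105 and 0.000934, and 0.544 for both with an estimated correlation. The monocyte mean was −0.24 ± 0.31, lower in 3 of 4 (1 down adjusted over the list alone, camera adjusted p = 0.142). Of 22 lists 13 passed camera, 7 higher and 6 lower. The count was 2 without the animal block, 1 without the discordantly dated arrays, 0 with them regrouped (limma; 275 at unadjusted p under 0.05), 259 with only the arrays compared, 35 after centring, 827 and 675 with the array SD and the erythroid mean as covariates, and after quantile normalization 64 higher and 198 lower (24.4% higher, against 43.8%). Without XHB it was 0 (limma; 1226 at unadjusted p under 0.05), without RWf7 3, without RSq8 9 and without RUe7 46.

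Whether the early and the late antibody changed blood differently was tested as the difference of the changes. Killer lymphocyte genes differed: GZMH changed by −0.39 in arm A and −2.81 in arm B (difference 2.42 ± 0.65, limma adjusted p = 0.0225), GNLY by 0.11 and −2.18 (2.29 ± 0.62, adjusted p = 0.0225) and CD8A by −0.48 and −1.81 (1.33 ± 0.45, adjusted p = 0.0363). The call of CD8A was lost without RLi6, RRf6, RSq8, RUe7 or XHB (limma adjusted p = 0.098, 0.118, 0.137, 0.0639 and 0.0833), without the doubted arrays of RZl5 (adjusted p = 0.0563), after quantile normalization (0.0799), with only the arrays compared (0.068), with arrays regrouped by date (0.162) and with the array SD (0.681) or the erythroid mean (0.417) as a covariate. The globin HBG2 and the granule gene LCN2 differed the other way, HBG2 with −3.02 in arm A and 0.36 in arm B (−3.38 ± 0.95, adjusted p = 0.0228) and LCN2 with −2.67 and 0.65 (−3.32 ± 0.97, adjusted p = 0.0243). The test called 2686 genes (1090 higher in arm A, 1596 lower).

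Of the cytotoxic genes 10 of 18 differed (15 adjusted over the list alone), mean 1.26. Of the NK cell genes 4 of 13 did (8 adjusted over the list alone), mean 0.89. These lists had camera adjusted p = 1.8e-06 and 0.00363, and 0.509 and 0.518 with an estimated correlation. Erythroid genes were lower in 4 of 15 (7 down and 1 up adjusted over the list alone), mean −1.25, and granule genes in 1 of 14 (1 adjusted over the list alone), mean −1.43 (camera adjusted p = 0.00243 and 0.00671; adjusted p = 0.668 and 0.646 with an estimated correlation). The references differ, 32 days before the arrays labelled day 63 in arm A and 11 days before day 182 in arm B, and measured from the uninfected sample in both arms 0 genes passed in limma (427 at unadjusted p under 0.05; CD8A 1.07, GZMH 1.41, GNLY 1.33, HBG2 −0.59 and LCN2 −0.81, adjusted p = 0.999 for each). The count was 1413 without the animal block (CD8A adjusted p = 0.0892), 64 with only the arrays compared, 4064 with arrays regrouped by date, 4612 without the doubted arrays of RZl5, and 0 in limma with the array SD (945 at unadjusted p under 0.05) or the erythroid mean (1420) as a covariate. Quantile normalization gave 340 higher and 967 lower (26% higher, against 40.6%), and centring, which moved the median of all genes from 0.0311 to 0.176, 1384 and 716 (65.9%). Without RRf6 the count was 0 (limma; 3559 at unadjusted p under 0.05), without RSq8 or RUe7 3, without RLi6 10, without RWf7 1231, without RPp6 1398 and without RZl5 6014.

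Over both early steps, from day 31 to the arrays of arm A labelled day 70, B cell genes rose. FCRLA rose by 1.10 ± 0.27, EBF1 by 1.02 ± 0.30, CD22 by 0.99 ± 0.24 and MS4A1 by 0.96 ± 0.30, each in 4 of 4 animals (limma adjusted p = 0.0323, 0.0441, 0.0345 and 0.0491). TOX (0.89 ± 0.23) and BTLA (0.83 ± 0.24) rose in 3 of 4 animals. HBG2 fell by 2.14 ± 0.67, XK by 1.61 ± 0.45 and ANK1 by 1.11 ± 0.30. In arm B, without antibody, EBF1 (0.73), MS4A1 (0.68) and CD22 (0.58) rose over these days in 4 of 4 animals. HBG2 changed by −1.67 there, and none of these passed the threshold. Between arms 0 genes differed (FCRLA by 0.62, limma adjusted p = 0.666). Of 12 B cell genes in arm A 9 rose (11 adjusted over the list alone), mean 0.76 ± 0.10. Erythroid genes fell in 2 of 15 (3 down and 1 up adjusted over the list alone), mean −0.75 ± 0.47. The granule mean was −0.85 ± 0.95, with 0 of 14 members past limma's threshold (0 adjusted over the list alone). These lists had camera adjusted p = 3.36e-05, 0.00202 and 0.00498, and 0.479, 0.668 and 0.619 with an estimated correlation. The fit called 731 genes (514 higher, 217 lower). It called 0 without the animal block (3782 at unadjusted p under 0.05), with the array SD (1282) or with the erythroid mean as a covariate (1466), 21 with only the arrays compared, 464 after quantile normalization (57.3% higher, against 70.3%), 4076 without the discordantly dated arrays, 4521 with them regrouped, and after centring 812 higher and 180 lower (81.9%). Without RLi6 or RRf6 it was 0 (limma; 3066 and 1628 at unadjusted p under 0.05), without RPp6 30 and without RZl5 3694.

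The corresponding late change, from day 171 to day 189 in arm B, gave 0 genes past limma's threshold (274 at unadjusted p under 0.05), 9 with only the arrays compared. CD8A and CD8B differed by −0.70 ± 0.32 and −0.97 ± 0.31 (limma adjusted p = 0.948 for both), lower in 4 of 4 animals, and CD8B passed with only the arrays compared (adjusted p = 0.0135) and with array weights (0.0227). The further probe sets changed by −0.72 (CD8A) and −0.44 (CD8B). With 0 members past the threshold, the cytotoxic mean was −0.41 ± 0.14, the interferon-stimulated mean −0.52 ± 0.27 and the monocyte mean −0.34 ± 0.26, each lower in 4 of 4 animals (0 adjusted over the list alone; camera adjusted p = 2.39e-06, 1.89e-11 and 6.05e-05, and adjusted p = 0.509, 0.485 and 0.485 with an estimated correlation). Higher in 4 of 4 animals were the erythroid mean (0.49 ± 0.41) and the granule mean (0.37 ± 0.21), also with 0 members past limma's threshold (0 adjusted over the list alone; camera adjusted p = 0.000182 and 0.0234, and adjusted p = 0.544 and 0.701 with an estimated correlation). Of 22 lists 7 passed camera, 3 higher and 4 lower.

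At day 70, 12 days after the antibody or the sham and 7 days into the drugs, the arms' changes from day 31 differed in 0 genes (limma; 938 at unadjusted p under 0.05). IFI27 changed by −0.81 in arm A and −2.61 in arm B (difference 1.81 ± 0.89, adjusted p = 0.649), and CD8A by −0.21 and −0.27 (0.05 ± 0.45, adjusted p = 0.979), a difference whose sign turned without RLi6 (−0.022), RRf6 (−0.16) or RWf7 (−0.25), and with the uninfected sample as the reference (−0.15). The comparison gave 0 genes with that reference (limma; 563 at unadjusted p under 0.05) and 0 with levels at day 70 and the hybridization batch as a block (466; CD8A −0.50), and 1 without XHB. Before treatment, the arms' changes from the uninfected sample to day 31 differed in 0 genes (limma; 137 at unadjusted p under 0.05), and in 1 without RZl5. Of 22 lists 7 passed camera at day 70 (3 higher in arm A, 4 lower) and 8 before treatment (5 higher, 3 lower), but 0 with an estimated correlation.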

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

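The tests of crossed labels, those that leave out arrays of RPp6 or RZl5, the covariate fits, the splits that keep the pairing of arrays and the search among unannotated probe sets were chosen after the result was seen. Chance marks about 1 in 20 groups of samples as holding an extreme sample, and 23 extreme samples were found in 273 groups tested.

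The number of genes past the threshold was higher at day 31 (5288) than at day 10 (3972) or day 14 (2901), and 4644 genes passed in the early depletion that starts from day 31. Narrower value distributions of the day 31 arrays are argued against as the whole cause, since quantile normalization, which gives all arrays one distribution, left 4929 genes at day 31 and 3013 in early depletion, and a median change of 0.284 against 0.326 among the 5288. A larger share of erythroid RNA at day 31 may account for part of it: with the erythroid mean as a covariate the count was 1757, below that of day 14, because the median change fell to 0.175 while its median SE went from 0.0973 to 0.0846. In early depletion the covariate left 0 genes (limma; 719 at unadjusted p under 0.05), with a median change of 0.106 against 0.448 and a median SE of 0.128 against 0.141, and the array SD as a covariate left 1704 genes at day 31 and 0 in early depletion (limma; 1251 at unadjusted p under 0.05), with median changes of 0.134 and 0.137. Over the 60 arrays, as deviations from each animal's mean, the array SD and the erythroid mean correlated (r −0.826, rho −0.866, permutation p = 1e-05 for each, the smallest the permutations can give, r −0.818 without the 2 arrays farthest from the median, −0.949 to −0.73 within an animal), so these covariates remove much of the same signal, and a change in red cells by day and a technical cause that moves both stay open.

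The arrays of RZl5 labelled days 63 and 70 ran opposite to those of the other arm A animals. CD8A on the array labelled day 63 was 11.9 (10.2 to 10.4 in the others). In early depletion AHSP changed by 0.322 (−2.83 to −2.55), CD274 by −0.278 (1.53 to 1.66), HBG2 by 0.154 (−4.5 to −3.78), TAP1 by −0.436 (1.19 to 1.48) and the erythroid list by 0.193 (−2.07 to −1.83). These changes start from RZl5's array labelled day 31, dated day 217, and a wrong reference stays open. From day 31 the array labelled day 63 correlated over genes (not independent replicates) with the others' mean day 63 and day 70 changes at r = −0.323 and 0.079, and that labelled day 70 at 0.488 and 0.215. From the uninfected array these were −0.117 and 0.555, and 0.647 and 0.436. Crossed labels may be the cause and stay open: from the uninfected array the crossed values (0.647 and 0.555) reached those of the other animals at these days as labelled (0.544 to 0.685 and 0.426 to 0.496), while from day 31 they (0.488 and 0.079) did not (0.756 to 0.795 and 0.582 to 0.794), and the mean of 9 unannotated probe sets described below rose by 0.252 from the array labelled day 63 to that labelled day 70, where it changed by −0.412 to −0.273 in the others. Failed depletion with correct labels stays open too, since the day 70 arrays of the other animals correlated with the day 63 change at 0.485 to 0.674 from day 31, around the 0.488 of RZl5, and at 0.116 to 0.378 from the uninfected array, below its 0.647, while a late response was not tested and no label was changed.

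The arrays of RPp6 labelled days 10 and 14 ran opposite to those of the other animals as well. The change at the label day 14 correlated with the others' day 10 change at r = 0.547 over genes and with their day 14 change at 0.168, and the change at the label day 10 with their day 14 change at 0.566 and their day 10 change at 0.449. As labelled, the other animals had 0.587 to 0.852 at day 10 and 0.651 to 0.789 at day 14, which neither the labelled nor the crossed values of RPp6 reached. At the label day 10 RPp6 had BST2 at 2.53 (1.16 to 1.7 in the others) and the handling list at 1.08 (0.0478 to 0.483), and at the label day 14 FCRL1 at 0.794 (−2.42 to −1.25) and the erythroid list at 1.04 (−2.14 to −0.788). Crossed labels may be the cause but stay open, and a slower course of infection in this animal was not tested.

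Other extreme samples lay apart from the rest of their group. In RPp6 CD8B on the array labelled day 70 was 8.51 (9.58 to 9.75 in the others) and MS4A1 changed by 1.32 in early recovery (0.807 to 0.87). In RZl5 TOX changed by −0.04 in early recovery (1.13 to 1.32). RWf7 had EBF1 at −0.0773 at day 10 (−1.21 to −0.731), CD8B at 0.95 at day 31 (−0.688 to 0.0243), and MX1 at 3.93 (2.9 to 3.04) and the interferon-stimulated list at 1.69 (1.37 to 1.43) at day 171. RUe7 had the platelet list at 1.27 at day 14 (0.305 to 0.58), IGF1R at −1.4 at day 171 (−0.442 to −0.353) and SPATS2L at −0.683 in late rebound (−2.32 to −2.08). S100A9 in RSq8 changed by −0.573 at day 14 (1.37 to 2.49). XHB had ACTN1 at 0.984 in late depletion (0.381 to 0.418) and the B cell list at 1.13 with drugs without antibody (0.0782 to 0.256).

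The changes after the early and the late antibody differed in 2686 genes by a test of the difference itself, but in 64 with only the arrays compared, 3 without RSq8 or RUe7, and 0 (limma) without RRf6 (3559 at unadjusted p under 0.05), from the uninfected sample (427) or with the array SD (945) or the erythroid mean (1420) as a covariate. A signal also appeared among probe sets that enter no test of genes: 9 probe sets that share 1 sequence record and have no gene annotation were higher than in the uninfected arrays by 0.594 on average at day 10 (8 of 8 animals), 0.916 at day 14 (7 of 7) and 0.298 at day 31 (8 of 8), with no p value given because they were picked in a search of such probe sets. The 11 other such records read for comparison (665 probe sets) changed by 0.071 to 0.155 at day 10, −0.119 to −0.013 at day 14 and 0.069 to 0.206 at day 31, where 8 of the 11 were higher in every animal, so a rise in every animal at day 31 was not particular to the 9.

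Other splits of the arrays into groups of the same sizes were counted, 100 drawn where there were more and 35 otherwise. Splits that keep the pairing, with each animal's arrays in different groups, were also counted, 100 drawn at days 10 and 31 and all 64 at day 14. Chance can be excluded at day 14 (2901, highest other 2799, and 2822 with the pairing kept and RPp6 crossed) and day 31 (5288, highest other 5, and 3768 with the pairing kept), where 1 split, the real one, gave as many genes, and at day 10 (3972, highest other 2044), where with the pairing kept 2 of 100 did (highest other 4430, with RPp6 and RWf7 crossed). For early against late depletion the splits were over the changes of 8 animals, fitted to those changes alone. That fit called 64 genes, not the 2686 of the main fit, and 1 of 35 splits, the real one, gave as many (highest other 0). It sets the arms apart for that smaller count only, and chance is not excluded for the 2686. The arms also differed in the time from reference to array. With the pairing kept, 16 splits in chronic infection and 8 in each comparison within 1 arm are too few for a share under 0.05. The real counts and the highest others among all splits and among these were 86, 29 and 3 in chronic infection, 32, 0 and 0 at day 171, 67, 2 and 0 in late depletion, 73, 17 and 0 in late rebound, 4644, 5691 and 5691 in early depletion (crossing only the arrays of RZl5), 95, 1203 and 1 with drugs without antibody, and 731, 982 and 7 in early recovery, and in the last 3 of these 2 of 35 splits gave as many. Where the real count was 0 in limma, all 35 splits are as large by construction and the count says nothing about chance. There the highest other split, also counted past the adjusted threshold, stands against that 0. It was 1726 in early rebound (again with RZl5 crossed) and 4333 at day 70 between arms (with RLi6, RPp6, RRf6 and XHB against the rest). For late recovery it was 0 and for the arms before treatment 14. The real groups had 1501, 938, 274 and 137 genes at unadjusted p under 0.05 in these comparisons, which is a different measure. Splits with many more genes than the real one point to a structure of the samples.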

How the results depend on the processing

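The fits without the arrays of RPp6 or RZl5, those with the array SD or the erythroid mean as a covariate and those with the uninfected sample as the reference were chosen after the data were seen. Over all alternatives, 179 of 309 counts of genes lay within 1.5 times the count as deposited and 130 did not, 164 of 198 CD8A and CD8B changes in the comparisons around the antibody kept their direction and side of the threshold, 24 lost and 9 gained a call, and 1 turned its sign. Of 967 list tests 783 kept direction and side and 184 lost the call, and of 3730 values of named genes 3052 kept them, 654 lost and 5 gained a call, and 19 turned sign. The median filter, no filter and the trend and robust options moved 0 counts by more than 1.5 times. Signal over background limits what can be said of dim genes, since no detection call is used here and genes under 5.01 log2 were not tested. The cause was not tested for any change given below unless stated. No alternative was left unrun, but the estimation of array weights did not converge.

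Without the replicate block (animal), day 14 had 1881 genes, chronic infection 21, day 171 9, drugs without antibody 6, late depletion 25, late rebound 2, early against late depletion 1413 and early recovery 0 (limma; 3782 at unadjusted p under 0.05). CD8B after the late antibody was −1.32 (adjusted p = 0.365 in limma) and CD8A in early against late 1.33 (adjusted p = 0.0892). The calls of CD8B at day 10 (adjusted p = 0.165 in limma) and of CD8A and CD8B at day 14 (0.126 for both) were lost too, and the block changed no other count by over 1.5 times and no other call of CD8A or CD8B. With the animal as a random block chronic infection had 51 genes, day 171 21 and drugs without antibody 42, and CD8B after the late antibody was −1.32 (adjusted p = 0.0943). With only the arrays compared, chronic infection and early depletion had 0 genes (limma; 1916 and 3508 at unadjusted p under 0.05), day 171 467, drugs without antibody 3, late depletion 291, late rebound 259, early against late 64, early recovery 21 and late recovery 9, CD8A in early against late was 1.33 (adjusted p = 0.068), and CD8B gained a call in late recovery (−0.97, adjusted p = 0.0135). These fits rest on fewer arrays, so the spread is estimated from those groups alone.

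All probe sets gave 12443 at day 10, 6742 at day 14, 16565 at day 31, 291 in chronic infection, 70 at day 171, 13200 in early depletion, 308 with drugs without antibody, 653 in late depletion, 356 in late rebound, 10247 in early against late and 2076 in early recovery, over more features tested. Quantile normalization gave 132 in chronic infection, 64 at day 171, 3013 in early depletion, 2 in early rebound, 262 in late rebound, 1307 in early against late, 1 at day 70 between arms and 464 in early recovery. CD8A gained a call in late rebound (1.13, adjusted p = 0.039 in limma) and lost it in early against late (1.09, adjusted p = 0.0799), and at day 31 CD8A and CD8B turned to 0.047 and 0.0035. Centring gave 57 in chronic infection, 14 at day 171 and 35 in late rebound. Array weights gave 7321 at day 10, 6730 at day 14, 878 in chronic infection, 1273 at day 171, 8580 in early depletion, 3048 in early rebound, 367 with drugs without antibody, 1867 in late depletion, 2230 in late rebound, 7976 in early against late, 4608 at day 70 between arms, 6987 in early recovery and 10 in late recovery. With them CD8A and CD8B were called in early depletion (−0.78 and −0.75), CD8A in early rebound (0.69) and late rebound (1.28), CD8B in early against late (0.74) and late recovery (−1.03), and CD8A at day 10 (−0.48).

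Without the discordantly dated arrays day 171 had 7 genes, late depletion 31, late rebound 1, early recovery 4076 and the arms before treatment 1, and CD8B after the late antibody was −1.36 (adjusted p = 0.122 in limma). With these arrays regrouped by date day 171 had 5, late depletion and late rebound 0 (limma; 660 and 275 at unadjusted p under 0.05), early against late 4064, day 70 between arms 1, early recovery 4521 and the arms before treatment 1. After the late antibody CD8A was then −1.43 and CD8B −0.98 (adjusted p = 0.603 and 0.884 in limma), and CD8A in early against late 0.98 (adjusted p = 0.162). Without the doubted arrays of RZl5, early rebound had 1434 genes and early against late 4612, with CD8A at 1.09 (adjusted p = 0.0563 in limma).

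With the array SD as a covariate day 31 had 1704 genes, chronic infection 234, day 171 69, early depletion, early against late and early recovery 0 (limma; 1251, 945 and 1282 at unadjusted p under 0.05), early rebound 68, late depletion 232, late rebound 827 and day 70 between arms 1. CD8A was 1.09 in late rebound (adjusted p = 0.0271 in limma) and 0.89 in early against late (adjusted p = 0.681), and turned to 0.17 at day 31 (CD8B 0.085), −0.011 at day 171 and −0.029 at day 70 between arms. With the erythroid mean as a covariate day 14 had 1864, day 31 1757, chronic infection 169, day 171 56, early depletion, early against late and early recovery 0 (limma; 719, 1420 and 1466 at unadjusted p under 0.05), early rebound 118, late depletion 345 and late rebound 675. CD8A was 1.28 in late rebound (adjusted p = 0.0188 in limma) and 0.99 in early against late (adjusted p = 0.417), and turned to 0.12 at day 31 (CD8B 0.099) and −0.074 at day 70 between arms. KLF1 and AHSP in early depletion turned to 0.10 and 0.26 there, as members of the list that the covariate removes, and the erythroid list has no value in this fit because its mean is fixed. With the uninfected sample as the reference early depletion had 550 genes and early against late 0 (limma; 427 at unadjusted p under 0.05), with CD8A at 1.07 (adjusted p = 0.999). A further CD8A probe set was −0.0037 in early rebound. At day 70 between arms CD8A was −0.15 from the uninfected sample and −0.50 with the hybridization batch as a block. With an estimated correlation 0 of 330 list tests passed in camera.

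Leaving out each animal in turn gave counts of 2024 to 5482 at day 10, 1831 to 3882 at day 14, 3269 to 6043 at day 31, 0 to 190 in chronic infection, 2 to 9 at day 171, 0 to 6926 in early depletion, 0 to 1493 in early rebound, 0 to 87 with drugs without antibody, 0 to 43 in late depletion, 0 to 46 in late rebound, 0 to 6014 in early against late, 0 to 1 at day 70 between arms, 0 to 3694 in early recovery, 0 to 0 in late recovery and 0 to 1 between arms before treatment. The animals that moved a count by over 1.5 times are named with each comparison above, and the remaining animals stay with the pooled spread. CD8A ranged from −0.68 to −0.33 in early depletion, 0.04 to 0.63 in early rebound, −2.15 to −1.54 in late depletion, 0.71 to 1.55 in late rebound and 1.06 to 1.68 in early against late, and CD8B from −0.69 to −0.35, 0.049 to 0.52, −1.59 to −1.06, 0.032 to 0.61 and 0.53 to 1.06. CD8A turned sign without RWf7 at day 171 (−0.16, with a range of −0.16 to 0.31), with drugs without antibody (0.036, range −0.57 to 0.036) and between arms before treatment (0.14, range −0.37 to 0.14). At day 70 between arms it turned without RLi6 (−0.022), RRf6 (−0.16) or RWf7 (−0.25), with a range of −0.25 to 0.35. Over all alternatives limma's adjusted p of CD8A ranged from 4.82e-08 to 0.603 after the late antibody and from 0.00186 to 0.999 in early against late, and that of CD8B after the late antibody from 2.01e-06 to 0.884.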

Other observations

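The reading of the 9 unannotated probe sets by group was chosen after the result was seen. Genes outside the lists also fell during infection (± SE of limma). BDKRB2, a bradykinin receptor, fell by 1.65 ± 0.18 at day 10, 1.93 ± 0.19 at day 14 and 1.43 ± 0.18 at day 31, in every animal with an array at that day (limma adjusted p = 2.2e-09, 3.24e-10 and 7.09e-07), and by 1.30 ± 0.25 at day 171 (limma adjusted p = 0.0108, 4 of 4 animals). The day 171 call of BDKRB2 was lost without RSq8, RUe7 or RWf7 (limma adjusted p = 0.145, 0.192 and 0.0913) and without the animal block (adjusted p = 0.551), while those at days 10, 14 and 31 held in every alternative run. SERPINE2, a protease inhibitor, and CPD, a carboxypeptidase, fell by 1.53 ± 0.25 and 1.58 ± 0.18 at day 10. WIF1 fell by 1.44 ± 0.23 at day 10, AXIN2 by 1.21 ± 0.16 at day 31 and CAMK4, a calcium-dependent kinase, by 1.12 ± 0.21 at day 31.

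The 9 probe sets that share 1 sequence record without a gene annotation were followed through the later samples. Their mean log2 level (± SD over animals) stood at 4.69 ± 0.06 in the 8 uninfected arrays, 5.29 ± 0.22 at day 10, 5.6 ± 0.45 at day 14, 4.99 ± 0.19 at day 31 and 4.66 ± 0.05 in chronic infection. In arm B it was 4.72 ± 0.12 at day 171, 5.02 ± 0.19 at day 182 after the late antibody, higher in 4 of 4 animals, and 4.71 ± 0.09 at day 189. The 11 other records without a gene annotation changed by −0.015 to 0.158 at day 182 against day 171, and 7 of them were higher in every animal. The most changed of the 9 rose from 3.85 ± 0.11 in the uninfected arrays to 8.24 ± 1.43 at day 14, and read 4.28 ± 0.50 at day 171, 5.70 ± 0.80 at day 182 and 4.08 ± 0.19 at day 189. In arm A the mean was 5.09, 5.26 and 4.92 on the arrays of RLi6, RPp6 and RRf6 labelled day 63 and 4.73, 4.85 and 4.64 on those labelled day 70, while RZl5 had 4.76 and 5.01. The record itself is not named here, and no hypothesis on it was tested.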
